A study of Homo sapiens with 2 samples.

How the data were processed

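Gene expression was measured in KON cells on 2 arrays, 1 for cells given a negative control DsiRNA and 1 for cells given a DsiRNA against LINC02154. Per the labels, 20 pmol of a DsiRNA (a short double-stranded RNA that Dicer cuts into a small interfering RNA) was delivered by lipid transfection, the cells were kept for 72 h, and 100 ng of total RNA was labelled with Cy3 by a one-colour kit. Each array carried 62976 spots of Agilent design 072363, whose probe coordinates refer to hg19 per the file headers.

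The deposited scanner output gives the intensity of each spot on a linear scale. Per the file headers, the authors read the arrays with Feature Extraction 10.7.3.1, with spatial and multiplicative detrending switched on and background method code 7 (the submitters' processing notes name Agilent Feature Extraction 10.7). The deposited intensity values are not scaled between arrays. A value table of the whole series was also deposited. Its columns have medians of 12.4 (control) and 11.9 (knockdown), and each of its 62976 rows lies within 0.496% of the processed intensity of the same spot, so it is on the linear scale, uncentred, and holds no ratio. Both arrays lie on 1 slide, so slide and group are not confounded, but position on the slide, labelling reaction and culture all go with the group.

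From the processed intensity, log2 was taken and each array's 75th percentile over its 60901 non-control spots was subtracted (252.3 on the control array and 220.4 on the knockdown array). Spots flagged as outliers were dropped (90 control, 83 knockdown), no spot was saturated, and repeat spots of a probe were averaged. Of 58201 probes, 26900 (46.2%) were well above background on the control array and 25625 (44.0%) on the knockdown array. Probe names were updated through a RefSeq gene table of a newer assembly (GRCh38.p14), used only for names and for which genes neighbour each other. Of the probes, 31104 matched 1 gene by accession, 3366 by symbol and 496 by an older symbol, and 23235 did not match. A gene was represented by its brightest probe among those well above background on both arrays, which gave 14706 measured genes, 12927 of them protein coding. Where a gene was above background on 1 array only, the bright array's scaled signal was set against the higher of the dim probe's own scaled signal and the lowest scaled signal among probes well above background on the dim array, and is given as "at least N-fold".

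With 1 array per group there is no spread between replicates. No test between the groups was run and no p-value is given. Percentiles among random lists and intervals over genes describe genes within these arrays, which are not replicates, and differences (knockdown minus control, log2) describe these 2 arrays, not the conditions. The technical spread was measured in 3 ways. Over the 286 probes printed 10 times and above background on both arrays, the median SD between spots was 0.06 log2 on each array and the SD of a difference between single spots was 0.099. Across the 4101 genes with 2 or more measured probes, the median SD between probes of 1 gene was 0.18 log2, and for 256 genes (6.24%) the probes differed by more than 1 log2. The 8 E1A spike-in probes differed by 0.045 ± 0.033 log2 (SD over probes) before scaling and by 0.24 after it. These errors cover spots, probes and hybridisation, not cultures, and the number of arrays limits the precision.

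Before the data were examined, 36 gene lists and the rule for named genes were fixed. A list is described by its measured members at least 2-fold higher or lower, its median log2 difference, and that median's percentile among 10000 random lists of the same size matched on mean signal in 20 bins; lists with under 5 measured members have no percentile. The named genes are LINC02154 and protein-coding genes within 1 Mb of it, the 12 protein-coding genes with the largest difference in each direction among those brighter than the median, the 4 largest "at least" folds of protein-coding genes per direction, the 2 highest and 2 lowest members of each main list and of each list outside the central 95% of random lists, members past 2-fold of any list, and CDKN1A, FOXM1, MKI67, MYC and TP63. Other genes and families are named as chosen after their values were seen. Levels of Y-linked genes and of XIST were left out. Some genes that the rule names are not reported here.

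The alternatives were normexp background correction with an offset of 50 on mean and local background intensity, median scaling, quantile and cyclic loess normalization, scaling on the spike-ins, the deposited value table, the mean over a gene's probes, only genes above the median signal, no background filter with scaled signals floored at 5, and thresholds of 1.5-fold and 3-fold. The code was tested on simulated data with the real signal levels of 14706 genes and noise of the size seen between probes. At the 2-fold threshold, 100.0% of 50 genes simulated with a 3-fold difference were called in the right direction, as were 4.0% of 50 genes simulated at 1.5-fold, and 0.0% of 14506 unchanged genes were called. A list of 40 genes shifted by 0.3 log2 lay at percentile 100.0 of its random lists, and 5.5% of unshifted lists fell outside the central 95%. The simulated noise was independent between genes, with an SD of 0.18 log2, so calls of unchanged genes at 2-fold were near excluded beforehand. Differences over the real measured genes had an SD of 0.555 log2. The simulation therefore checks the code, and gives no error rate for the real calls or random ranges. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.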

Results

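KON cells, an established line from a human oral squamous cell carcinoma, were compared 72 h after transfection with a DsiRNA against LINC02154, a gene for a long intergenic noncoding RNA, or with a negative control DsiRNA. The question was how the expression profile of the cells differs when LINC02154 is targeted. Each group had 1 array, so no value below has a replicate error. Differences are knockdown minus control in log2 of the scaled signal, and fold values come from the same scale. Of the 58201 probes, 46.2% were well above background on the control array and 44.0% on the knockdown array. Across the 14706 genes measured on both arrays, the arrays correlated with r = 0.98 (across genes, which are not independent replicates).

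The targeted RNA itself could not be checked, because 0 probes carry the name LINC02154, its synonym or its accession. In the RefSeq table the gene lies between FAM9C and ATXN3L, and 4 unnamed or transcript-named probes lie between these genes in the array's hg19 coordinates. Only 1 of them was well above background. It is listed as ENST00000443965 (hg19 chromosome X, 13284754 to 13284813, minus strand), and its signal was 251.4 on the control array and 77.9 on the knockdown array, a scaled difference of -1.49 (2.82-fold lower). Whether this probe reads LINC02154 is not established by the files, and the probe was singled out after its values were seen. Of the 14 protein-coding genes within 1 Mb of LINC02154, 7 were measured and 0 differed by 2-fold. GEMIN8 had a difference of -0.71, TRAPPC2 of -0.48, TCEANC of -0.40, TMSB4X of -0.35, PRPS2 of -0.32, RAB9A of 0.21 (-0.02 with spike-in scaling) and OFD1 of 0.33.

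In the knockdown array, genes of the immediate early and heat shock responses and of keratinocyte differentiation were higher, and genes of mitosis were lower. Of the measured genes, 654 (4.45%) were at least 2-fold higher and 427 (2.90%) at least 2-fold lower, among them 589 and 382 protein-coding genes. At 4-fold or more, 58 genes were higher and 15 lower. The largest positive differences among brighter protein-coding genes were those of HSPA6, an inducible HSP70 chaperone (5.58-fold higher), KRT6B, a keratin of activated and wounded epithelium (5.49-fold), IFNL2, a type III interferon (5.35-fold), OVOL1, a transcription factor of epidermal differentiation (5.04-fold), KLF2 (5.03-fold) and FOSB (5.01-fold). They were followed by the HSP40 co-chaperones DNAJB6 (2.28, with probes from 0.77 to 2.30) and DNAJA4 (2.16), the gastrin gene GAST (2.17), NCF1 (2.16) and SH2D3C (2.14). KRT6B, IFNL2 and NCF1 have near-identical copies, so their probes may also read those. The largest negative differences were those of KIF20A, a kinesin of cytokinesis (4.74-fold lower), ANLN, the gene for the contractile ring protein anillin (3.84-fold), EPDR1 (3.38-fold), DUT, the dUTPase that keeps uracil out of DNA (3.34-fold), and ALDH3A1, an aldehyde dehydrogenase (3.22-fold). PIF1 (-1.67), TMBIM4 (-1.65), CCNB1 (-1.64), CDKN3 (-1.63), SLC47A2 (-1.62), FAM216A (-1.57) and EEA1 (-1.55) completed the 12.

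The split of these calls depends on the scaling. Higher genes made up 60.5% of the calls in the main setting, 40.8% with median scaling (467 higher, 679 lower), which moved the median of all genes from -0.01 to -0.13, and 26.5% with spike-in scaling (356 higher, 988 lower), which moved it to -0.24. These scalings move each gene, and each list median, by the same amount. With normexp background correction 319 genes were higher and 186 lower. Besides genes for which this is stated below, ATF3, CCL5, CCNE1, CHAC1, COL4A2, DNAJA1, E2F1, HSP90AA1, LIF, MRPL19, MRPL24, MTHFD2, RPL3, SKIL and VEGFA lay under 2-fold in at least 1 other setting.

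**Figure D1:**
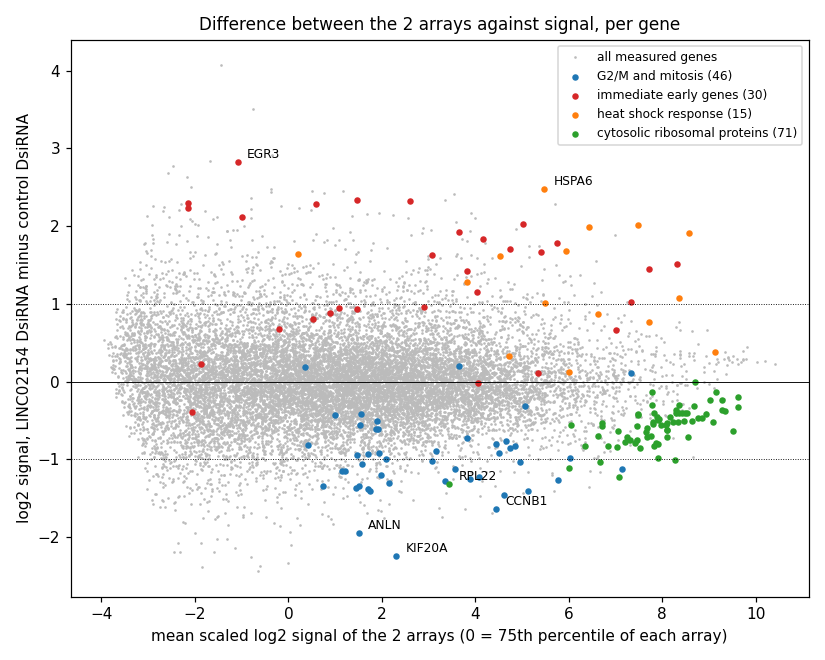
Difference in log2 signal (LINC02154 DsiRNA minus control DsiRNA, 1 array each) against the mean scaled log2 signal of both arrays, 1 point per measured gene, with 4 gene lists in colour and dotted lines at 2-fold. Heat shock genes (median 1.28) and immediate early genes (median 1.48) lie above 0 and G2/M genes (median -1.005) below it over a wide range of signal, while ribosomal protein genes (median -0.54) lie below 0 at the bright end.

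Cell cycle genes differed by phase. Of the 46 measured genes of G2/M and mitosis, 23 were at least 2-fold lower, 0 were at least 2-fold higher and 43 lay below 0; 35 were at least 2-fold lower with spike-in scaling. Their median of -1.005 lay at percentile 0.00 of the random lists, whose central 95% ran from -0.16 to 0.13. Besides KIF20A and ANLN, the cyclin genes CCNB1 (-1.64), CCNB2 (-1.40) and CCNA2 (-1.15), the mitotic kinase genes PLK1 (-1.37), AURKA (-1.23) and BUB1B (-1.34), and FOXM1, the transcription factor of G2/M genes (2.54-fold lower), were lower. The proliferation marker gene MKI67 had a difference of -0.42, with probes from -1.14 to -0.42. At the other end of the list stood HMMR (0.21) and MYBL2 (0.19), which lay at -0.03 and -0.04 with spike-in scaling. The 42 genes of G1/S and DNA replication had a median of 0.13 (percentile 96.1, within the random range), or -0.11 with spike-in scaling. Of these, 3 were at least 2-fold higher and 0 lower, against 1 higher with normexp, and 1 lower with median or spike-in scaling. E2F2 (1.40) and E2F1 (1.39), activators of S-phase genes, and CCNE1 (1.00), the cyclin of the G1/S transition, were the higher ones, while TYMS (-0.93) and RRM1 (-0.67), enzymes of nucleotide synthesis, had the lowest values. Histone genes of the replication-dependent class had a median of -0.31 over 49 genes (percentile 0.01), with H1-5 (-1.26), H1-3 (-1.07) and H2BC7 (-1.05) at least 2-fold lower (0 members with normexp, 8 with spike-in scaling). The 39 of them brighter than the median gene had a median of -0.06 (percentile 31.2, within the random range), and the mean over probes gave -0.19 for all 49. Probes of these near-identical genes may read several members. Genes of homologous recombination and Fanconi repair had a median of -0.16 over 27 genes, within the random range.

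CDKN1A, the gene for the CDK inhibitor p21, was 2.06-fold higher (1.04), but under 2-fold with normexp (0.95), median scaling (0.91) and spike-in scaling (0.80). The 28 measured p53 targets had a median of 0.25 (percentile 99.5, outside the random range), or 0.02 with spike-in scaling, which is 0.26 above the median of all genes in that setting. PLK3 (1.49), ZMAT3 (1.14, or 0.41 with normexp and 0.91 with spike-in scaling) and CDKN1A were at least 2-fold higher, 0 were lower, and TP53I3 (-0.58) and FAS (-0.52) had the lowest values. CDK inhibitors and D cyclins had a median of 0.14 over 8 genes (-0.10 with spike-in scaling), within the random range, and CDKN1A was the only member past 2-fold in the main setting. This list pools inhibitors of the cell cycle with cyclins that drive it, so its median gives no direction for the cycle. In the BCL2 family and apoptosis list the median was 0.25 over 24 genes (percentile 99.3), or 0.13 with median scaling and 0.017 with spike-in scaling. That list pools genes that promote apoptosis with genes that inhibit it, so its median gives no direction for apoptosis. APAF1, the apoptosome scaffold, was 3.40-fold higher at low signals of 25.7 and 76.3 (log2 difference 0.80 with normexp, under 2-fold), BIRC3, an inhibitor of apoptosis, was 2.91-fold lower, and the BH3-only gene BBC3 had a difference of 0.81.

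Mitochondrial genes showed small differences. None of the 75 measured nuclear-encoded oxidative phosphorylation genes differed by 2-fold (0 higher, 0 lower), but 62 lay below 0. Their median of -0.20 lay at percentile 0.05 of the random lists (central 95% from -0.13 to 0.10). NDUFB5 (-0.84) and ATP5MC2 (-0.62) were lowest, and SDHA (0.37) and NDUFB3 (0.18, or -0.05 with spike-in scaling) highest. The 11 measured mitochondrially encoded genes had a median of -0.26 (percentile 4.76, within the random range), with ND3 at -0.94 and ND6 at 0.81. Genes of the mitochondrial ribosome had a median of -0.23 over 73 genes (percentile 0.00). In that list MRPL19 (-1.01, with probes from -1.88 to -1.01) and MRPL24 (-1.01) were at least 2-fold lower and MRPL18 was 2.94-fold higher, while 0 members were at least 2-fold lower with normexp or cyclic loess and 5 with spike-in scaling. The tricarboxylic acid cycle list, which also holds genes of cytosolic enzymes such as IDH1, had a median of -0.23 over 22 genes (percentile 2.39). SUCLG2 (-1.34, or -0.90 with normexp) and the cytosolic IDH1 (-1.11) were at least 2-fold lower, and DLAT (0.55) was highest. The list lay within the random range with normexp (-0.21) and without the background filter (percentile 2.90). Mitochondrial biogenesis and dynamics genes had a median of -0.15 over 29 genes, within the random range, but lay outside it without the background filter (-0.22) and among the 20 brighter than the median gene (-0.29). Glycolysis genes had a median of -0.34 over 22 genes (percentile 0.11). GAPDH was 2.23-fold lower, ALDOA had a difference of -0.75, and PGAM1 (1.07) was at least 2-fold higher, though not with median or spike-in scaling or with the mean over its probes.

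The greatest list medians were those of stress and signalling genes. Of the 30 immediate early genes, 19 were at least 2-fold higher and 0 lower, with a median of 1.48 (percentile 100.0, random range -0.21 to 0.18). EGR3 was 7.10-fold higher, EGR1 (1.79), FOS (1.92) and JUN (1.83), transcription factors induced within minutes of a stimulus, and the phosphatase genes DUSP1 (2.03), DUSP5 (1.63) and DUSP6 (1.67) were also at least 2-fold higher. SPRY4 (2.12) was higher too, with probes from 0.40 to 2.12. ETV4 (-0.39) and PHLDA1 (-0.02, or 0.03 with cyclic loess) were the lowest members, and MYC had a difference of 0.11 (-0.13 with spike-in scaling). Of the 15 heat shock genes, 10 were at least 2-fold higher and 15 lay above 0, with a median of 1.28 (percentile 100.0). Besides HSPA6 these were HSPA1B (4.02-fold) and HSPA1A (3.75-fold), whose probes cannot be assumed to tell the copies apart, HSPH1 (1.98), DNAJB1 (1.69), CRYAB (1.65), HSPA8 (1.62), BAG3 (1.28), HSP90AA1 (1.08) and DNAJA1 (1.01). HSF1, the regulator of the response, had a difference of 0.13 (-0.11 with spike-in scaling).

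**Figure D2:**
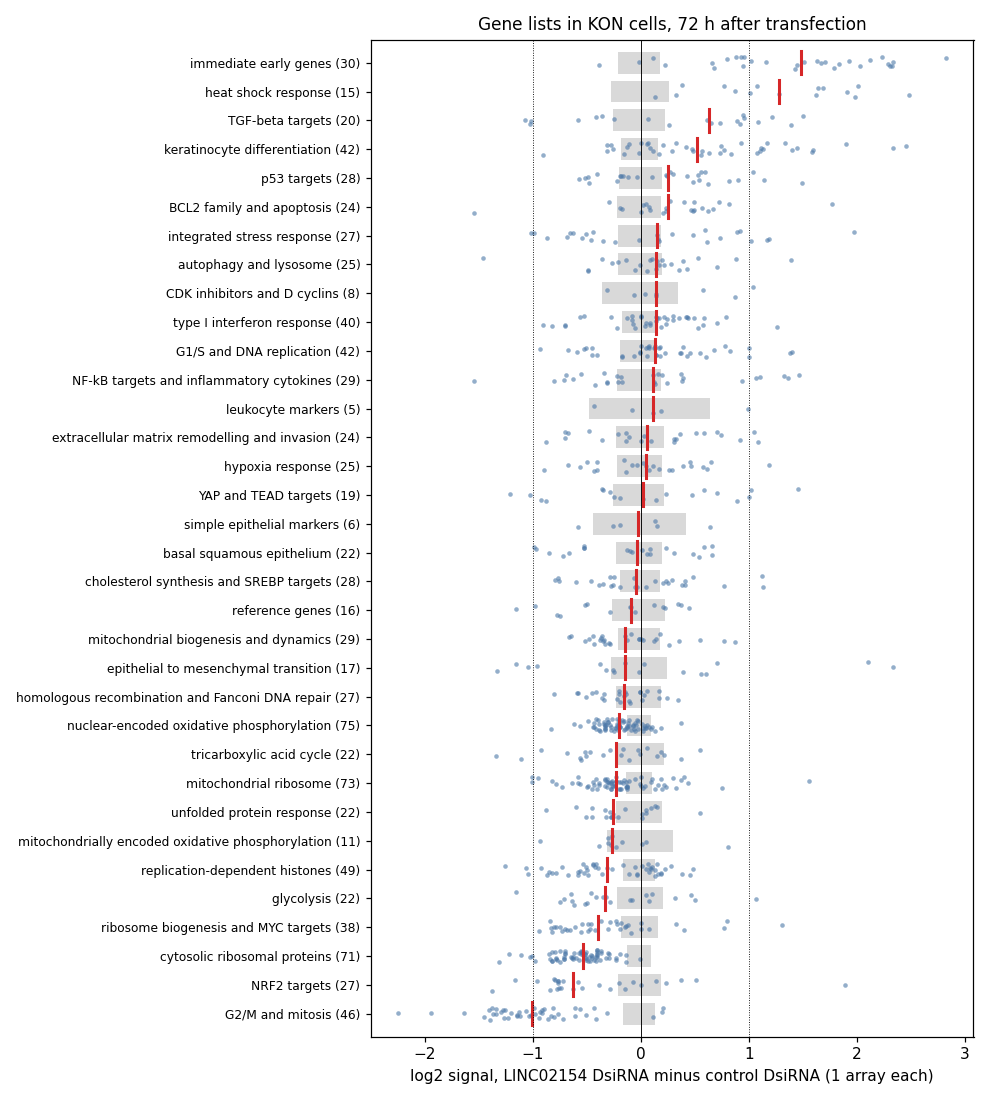
Log2 difference (LINC02154 DsiRNA minus control DsiRNA, 1 array each) of each measured member of the 34 lists with at least 5 measured members, whose number stands in brackets. Red bars are list medians, grey bands the central 95% of medians of 10000 random lists matched on size and signal, and dotted lines mark 2-fold; 16 medians lie outside their band, from -1.005 for G2/M and mitosis to 1.48 for immediate early genes.

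Genes of keratinocyte differentiation were higher as a group. Of the 42 measured, 13 were at least 2-fold higher and 0 lower (7 higher with normexp, 8 higher and 1 lower with spike-in scaling), and the median was 0.52 (percentile 100.0, random range -0.18 to 0.16). They included KRT6B, OVOL1, KRT16 (1.59), the protease gene KLK11 (1.90), and the cornified envelope genes SPRR2E (1.59), SPRR3 (1.45, or 0.60 with normexp), SPRR2A (1.33) and SPRR1B (1.17, or 0.79 with normexp and 0.94 with spike-in scaling), which belong to a family of similar copies. KRT1, KRT10, IVL, FLG and TGM1, also on the list, were not among the 13. Of the 18 members brighter than the median gene, 4 were at least 2-fold higher. CSTA (-0.91) and KRT80 (-0.32) had the lowest values. Basal squamous genes had a median of -0.03 over 22 genes (0.005 with cyclic loess), within the random range, and TP63, the basal lineage regulator, had a difference of 0.54. The list of TGF-beta targets, which also holds ligand and receptor genes of the pathway, went both ways around a median of 0.63 over 20 genes (percentile 100.0). At least 2-fold higher were 4 members, among them SMAD7 (2.82-fold), ID2 (1.39) and SKIL (1.22). The receptor gene TGFBR1 (-1.07, or -0.64 with normexp), the ligand gene TGFB2 (-1.03, or -0.50 with normexp) and COL4A2 (-1.02) were at least 2-fold lower. With spike-in scaling 2 were higher, and with normexp 1 was lower. In the epithelial to mesenchymal transition list (median -0.15 over 17 genes, within the random range) SNAI1, a repressor of E-cadherin, was 4.29-fold higher and OVOL1 was higher as above, while CDH2 (-1.33, with probes from -1.33 to -0.79, or -0.77 with normexp), CLDN1 (-1.15) and ESRP1 (-1.05) were lower. The list pools epithelial and mesenchymal genes, which a transition would move in opposite directions, so its median cannot show a transition. Extracellular matrix remodelling genes had a median of 0.06 over 24 genes, within the random range, or -0.18 with spike-in scaling. The 13 of them brighter than the median gene had a median of 0.36 (percentile 99.2, outside the random range). YAP and TEAD targets had a median of 0.02 over 19 genes, or -0.22 with spike-in scaling, within the random range.

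Ribosomal genes were lower as a group. All 71 measured cytosolic ribosomal protein genes lay below 0 in the main setting (RPL31, at -0.01, lay at 0.07 with cyclic loess), with a median of -0.54 (percentile 0.00, random range -0.13 to 0.10). RPL22 (2.49-fold lower), RPS4X (-1.22), RPS3 (-1.11) and RPL3 (-1.03) were among the 5 that were at least 2-fold lower (15 with spike-in scaling and 3 with cyclic loess), and probes of these genes may also read processed pseudogenes. The 38 genes of ribosome biogenesis and MYC targets had a median of -0.40 (percentile 0.00), or -0.23 over those brighter than the median gene. NME1 (-0.95) and UTP20 (-0.84) were lowest, and NOP58 (1.31) was at least 2-fold higher (6 members at least 2-fold lower with spike-in scaling). NRF2 targets, genes of antioxidant defence, had a median of -0.63 over 27 genes (percentile 0.00). NQO1 was 2.60-fold lower and UGDH (-1.16) was lower (10 members past 2-fold lower with spike-in scaling), whereas HMOX1, the heme oxygenase gene, was 3.70-fold higher. The unfolded protein response had a median of -0.26 over 22 genes (percentile 1.17), with HYOU1 at -0.88, HSPA5 at -0.60 and HERPUD1 at 0.55, and 0 members past 2-fold. With quantile normalization its median of -0.21 lay within the random range.

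The type I interferon response had a median of 0.14 over 40 genes (percentile 96.7, within the random range), or -0.10 with spike-in scaling. With the mean over a gene's probes it was 0.17 and lay outside the random range (percentile 98.0). ISG20 (1.26) was at least 2-fold higher, ISG15 had a difference of 0.79, and CXCL10 (-0.83, with probes from -0.83 to 0.06) was among the lowest. CXCL10 was dim (signals of 40.1 and 19.8), and lay at -0.16 with normexp, -0.38 with the mean over its probes and -1.06 with spike-in scaling. Of the interferon list, 1 member was at least 2-fold lower with median scaling and 2 with spike-in scaling. NF-kB targets and inflammatory cytokines had a median of 0.12 over 29 genes, within the random range, or -0.12 with spike-in scaling and -0.18 with the mean over a gene's probes. CSF2 (1.46), CCL20 (1.36), IL36G (1.32), LIF (1.10) and CCL5 (1.06) were at least 2-fold higher and BIRC3 lower. With normexp, median or spike-in scaling 3 members were higher. The integrated stress response had a median of 0.15 over 27 genes (within the random range), or -0.09 with spike-in scaling, with NUPR1 (3.94-fold higher), VEGFA (1.18), CHAC1 (1.17) and ATF3 (1.02) higher and MTHFD2 (-1.02) lower. With spike-in scaling 1 member was higher and 3 lower. Medians within the random range were also found for cholesterol synthesis (-0.05 over 28 genes), hypoxia (0.05 over 25 genes, or -0.19 with spike-in scaling) and autophagy and lysosome genes (0.14 over 25 genes, or -0.09 with spike-in scaling). In the last of these CTSB (-1.46) was at least 2-fold lower and MCOLN1 (1.39) higher, though under 2-fold with normexp.

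Markers of other cell types were few and showed no common direction. Of 12 fibroblast markers 4 were measured, with THY1 at 1.32 (0.52 with normexp) and ACTA2 at -1.86. Of 10 endothelial markers 3 were measured and 0 differed by 2-fold. The 5 measured leukocyte markers had a median of 0.11 (-0.13 with spike-in scaling) and the 6 measured simple epithelial markers one of -0.03 (0.015 with cyclic loess), both within the random range. The 16 reference genes had a median of -0.10, and GAPDH was the only one past 2-fold.

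Some genes were well above background on 1 array only, 284 on the knockdown array and 709 on the control array. By the bound, 129 of them were at least 2-fold higher and 66 at least 2-fold lower. The lowest scaled signal above background was -4.21 on the control array and -3.82 on the knockdown array. A lower gene was thus set against the higher floor, and the counts in the 2 directions are not on equal terms. Among protein-coding genes, the largest bounds were these. CERS1 was at least 8.07-fold higher (its transcript overlaps GDF1), COL2A1 at least 5.97-fold, MLC1 at least 5.95-fold and CHRNA1 at least 5.72-fold. BHLHA15 was at least 15.9-fold lower, STMP1 at least 4.64-fold, BPIFB1 at least 4.35-fold and ACSM3 at least 4.33-fold.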

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

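The tests in this part were chosen after the results were seen. Signal in probes that the comparisons do not use was marked for a closer look. Of the 4867 probes without a current gene name that were above background on both arrays, 234 (4.81%) were at least 2-fold higher in the knockdown array and 114 (2.34%) at least 2-fold lower, shares close to those of named genes (4.45% and 2.90%). The probe listed as ENST00000443965, between FAM9C and ATXN3L, is among the lower ones.

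Immediate early and heat shock genes were higher together in the knockdown array: 43 of the 45 members lay above 0. The lower of the 2 list medians stayed at 1.05 log2 or more under 5 other scalings and background corrections. Median and spike-in scaling add a constant much smaller than these medians, so they could hardly have removed the pattern. Normexp, quantile and cyclic loess can change genes unequally. With them the heat shock median, the lower of the 2, was 1.21, 1.28 and 1.33, which argues against those steps alone as the source. More degraded RNA in the knockdown sample would leave probes near the 3' end higher than 5' probes of the same gene, but over 3857 genes with 2 probes at least 200 bases apart the median of the 3' minus the 5' difference was -0.049 (95% bootstrap interval -0.06 to -0.04). A stress of 1 culture, such as handling at harvest, and a response to the DsiRNA or to the loss of LINC02154 both need the 43 members above 0, so these cannot be told apart with 1 culture per group. The response to LINC02154 loss stays open, as untested.

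G2/M genes were lower in the knockdown array. The list median stayed at -0.97 or below under the 5 other scalings and background corrections. Median and spike-in scaling lower all genes by a constant here, so they could only lower it. With normexp, quantile and cyclic loess, which can change genes unequally, it was -1.02, -1.01 and -0.97. These values argue against those steps as the source. In 100.0% of the 9 G2/M genes with 2 or more probes each probe lay below 0, which argues against misreading by single probes in those genes. KIF20A, ANLN and FOXM1, among others, had 1 measured probe and could not be checked in this way. A difference between cultures other than the DsiRNA, such as density or growth, needs the same 43 genes below 0 as an effect of the DsiRNA, and these cannot be told apart with 1 culture per group. An effect of the DsiRNA against LINC02154 stays open, as untested.

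Cytosolic ribosomal protein genes were lower in the knockdown array, at the bright end of the signal range. Loss of signal in bright probes would lower other bright genes alike, but 142 genes outside the ribosomal and translation factor families, at least as bright as the lower quartile of the list, had a median of 0.21. Genes named EEF, left out of the 142, were lower too (median -0.72 over the 9 brighter than the median gene). Heat shock and immediate early genes, which were higher, were not left out, so the 0.21 depends on this choice. The list median stayed at -0.47 or below under the 5 other scalings and background corrections. Of these, median and spike-in scaling could only lower it. It was -0.58 with normexp, -0.51 with quantile normalization and -0.47 with cyclic loess. An effect of the DsiRNA and a difference in growth between the cultures both stay open, and neither was tested.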

How the results depend on the processing

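All alternatives were planned before the data were examined, except those of the ENST00000443965 probe and of the families chosen after their values were seen. The 140 named genes past 2-fold kept their direction in all 1223 values under the alternatives, but 30 were under 2-fold with normexp, 24 with spike-in and 16 with median scaling. Many of these values could hardly have reversed. Median and spike-in scaling add a constant well under 2-fold, the deposited value table holds nearly the same intensities, and the filter settings reuse the main values. Of the 16 lists outside the random range, 13 stayed outside it in every setting with the same direction relative to all genes. The tricarboxylic acid cycle, unfolded protein response and histone lists did not. Median and spike-in scaling shift a list and its random lists alike, so in those settings staying outside only repeats the main result. The interferon, mitochondrial biogenesis and extracellular matrix lists moved outside it in some setting. No list outside the random range and no named gene past 2-fold reversed. Among list medians 229 of 304 values moved by less than the SD of random lists, and among single genes 1204 of 1669 by less than the 0.099 log2 of single spots. Numbers of higher and lower genes were 1857 and 1708 at 1.5-fold, 147 and 55 at 3-fold, 319 and 186 with normexp, 261 and 129 among genes above the median signal (fewer genes), and 1269 and 924 without the background filter (more genes); 679 were lower with median scaling, and 356 were higher and 988 lower with spike-in scaling. Every gene called with normexp in the higher direction (319) and 177 of the 186 lower ones were called in the main setting; the offset shrinks differences of dim genes.

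Median and spike-in scaling move all genes by a constant, which explains their shifts. With median scaling the list medians were 0.0016 for G1/S, -1.13 for G2/M, -0.33 for nuclear oxidative phosphorylation, 0.13 for p53 targets, 0.014 for type I interferon, 0.39 for keratinocyte differentiation, 1.35 for immediate early genes and -0.66 for cytosolic ribosomal proteins. With spike-in scaling they were -0.11, -1.24, -0.44, 0.017, -0.10, 0.28, 1.24 and -0.77 in the same order, -0.50 for mitochondrially encoded genes and 1.05 for heat shock. Normexp gave 0.40 for keratinocyte differentiation and 1.27 for immediate early genes, the filter at the median signal 0.40 for keratinocyte differentiation, and cyclic loess -0.47 for ribosomal proteins; the cause was not tested. The log2 difference of the ENST00000443965 probe was -1.08 with normexp and -1.73 with spike-in scaling, alternatives chosen after seeing the data. LINC02154 has no named probe, so the alternatives foreseen for it gave no value. No paired analysis was possible because each group has 1 array. Signal over background limits dim genes most: the error of a difference from Feature Extraction's error model, which is wider than the SD between repeat spots, was 0.20 log2 for bright named genes and up to 0.39 for dim ones.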

Other observations

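Gene families in this part were chosen after their values were seen, and no test was planned for them. Interferon genes of type III and the type I interferon gene IFNB1 were higher in the knockdown array: IFNL1 had a difference of 1.70, IFNL2 of 2.42 and IFNL3 of 2.45, with signals of 153.9 and 736.1 for IFNL3 on the control and knockdown arrays. IFNB1 was well above background on the knockdown array only, at least 5.69-fold higher by the bound. IFNL2 and IFNL3 are near-identical, so their probes may read both, and the median of the 3 IFNL genes was 2.18 with spike-in scaling.

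Other families were taken by the start of their gene names. All 12 measured genes with names starting in AKR (aldo-keto reductases and some of their pseudogenes) lay below 0, with a median of -0.75 (percentile 0.00 of random lists) and 0 past 2-fold, and AKR1B10, at a signal of 34544 on the control array, had a difference of -0.96. The NRF2 target list also holds AKR1B10, AKR1C1, AKR1C2 and AKR1C3, so the AKR and NRF2 results overlap. Whether probes of similar AKR genes tell them apart was not checked. Aldehyde dehydrogenase genes had a median of -0.48 over 15 genes (percentile 0.11), led by ALDH1L1 (-1.70), ALDH3A1 (-1.69) and ALDH5A1 (-1.44), with 4 at least 2-fold lower and 3 above 0 (ALDH1A3 at 0.12, ALDH3B1 at 0.12 and ALDH4A1 at 0.40). Genes with names starting in EEF, mostly elongation factors but also a kinase and methyltransferases that modify them, had a median of -0.50 over 13 genes (percentile 0.12), with EEF1A1 at -0.96 and EEF1G at -0.90. Genes with names starting in SEMA, which include the antisense RNA SEMA3B-AS1 (1.43), had a median of 0.38 over 16 genes (percentile 99.4), 0.15 with spike-in scaling, 0.89 over the 4 brighter than the median gene and 0.00 over 24 without the background filter, with SEMA7A at 1.83 and SEMA4C at 1.04. Genes named ZNF had a median of 0.12 over 424 genes and SNORD genes one of 0.15 over 94 genes, and both medians lay below 0 with spike-in scaling (-0.12 and -0.08), as did ZNF with median scaling (-0.01).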
